A study of Rattus norvegicus with 2 samples.

How the data were processed

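The data were 1 table of m6A peaks from 2 libraries of lead-exposed rat hippocampal neurons, 1 IP and 1 input, grouped by their sample titles. Per the labels' protocols, total RNA was extracted, m6A-containing RNA was immunoprecipitated with a commercial kit, and libraries were made with a directional RNA kit. The submitters' processing notes name cutadapt 1.9.3, STAR and HISAT2 2.0.4, without saying which step each served. The peak names and columns, per the file headers, are those of MACS, a peak caller that compares the IP with a local background; its version and thresholds, the genome build and the annotation are not given in the sources used here.

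Each row gave a region, a transcript, a gene name, a fold enrichment, a p-value and a false discovery rate. Fold enrichment was a linear ratio of the IP over the background, as deposited. The p-value was deposited as a score, 10 times the −log10 of p, per the file headers, and a second score column repeated it in all 8512 rows. Among the scores, 168 peaks stood at exactly 3100 and 7 above it, up to 3213.87. The value 3100 is called the cap because so many peaks share it, although it was not a strict maximum. The false discovery rate was deposited as a percent and stood at 100 throughout, so it separated no peak, and p was used in its place. Region length equalled end minus start in all rows, so starts were read as counted from 0 and are printed 1 higher. Peak numbers ran up to 14090, so the table appears to hold part of the peaks called. All listed peaks were tied to transcripts (6771 on RefSeq and 1741 on Ensembl transcripts). Why other numbers are absent is not given in the sources used here. There were 1575 regions shorter than 100 bases. No position in the table was compared with another build.

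Genes were named through a RefSeq gene table of assembly GRCr8, by symbol (7761 peaks), gene ID (459) or transcript accession (23); 269 peaks were not matched and kept the deposited name. In 10 peaks the deposited name and gene ID pointed to different genes, and the name was followed. Current chromosomes were used only to count peaks whose gene now lies on another chromosome (81 peaks of 59 genes). Peaks with a provisional name (409), no match or another chromosome, 533 in all, are called doubtful names.

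Before the data were examined, the following were fixed: 21 gene lists, the results, the alternatives and the rule for named genes. The rule takes the 10 genes with the highest single-peak fold and the 10 with the most peaks, leaving out provisional names, up to 4 members of each list with the highest fold, and members of the PI3K-AKT core and m6A machinery without a peak. Genes named outside it are said to be so, and some genes that the rule takes are not reported here. For each list, the share of members with a peak was given with an exact (Clopper-Pearson) 95% interval and set against 10000 random lists of the same size drawn from 23154 protein-coding genes. The median over listed members of each gene's highest fold, with an order-statistic 95% interval, was set against 10000 random lists of listed genes matched on peak number (5 classes: 1, 2, 3, 4 to 5, and 6 or more), where at least 5 members were listed. Percentiles at or above 97.5 or at or below 2.5 are called outside the random range. These percentiles describe these libraries; no p-value of a comparison between groups was computed, and intervals cover counting error only. On simulated data with 200 lists of 30 genes among 4209, lists raised 1.5-fold were placed above the upper bound in 84.5% of cases, lists raised 2-fold in 99.5% and unchanged lists in 1.5%. Most lists had fewer than 30 listed members, and lists of such sizes were not simulated. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

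Because no genome or annotation of the table's build was used here, 4 planned items were not run: the place of peaks within transcripts, the m6A sequence motif around peak centres, the relation of peak number to gene length, and the matching of lists on exonic length, so list shares were set against unmatched random lists. Strand is not a column of the table, so regions were merged without it. Alternatives tried were stricter p limits, a fold minimum, merged regions, the mean instead of the highest fold per gene, unmatched random lists, and, added after the data were seen, a p of at most 1e-5 and the removal of doubtful names. Also after the strongest peaks had been seen, a list of 51 genes of glutamate- and lysine-rich proteins was written, leaving out genes already seen at the top, before the values of its members were seen.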

Results

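Adenosine methylation at the N6 position (m6A) was profiled in primary hippocampal neurons of newborn Sprague-Dawley rats that had been exposed to lead acetate (PbAc) for 48 h from day 12 in vitro. The cultures had received AraC on day 7 in vitro. The method was methylated RNA immunoprecipitation followed by sequencing, in which fragmented RNA is pulled down with an antibody against m6A and compared with the RNA that went into the pull-down. The 2 libraries analysed here were 1 immunoprecipitate (IP) and 1 input, both from exposed neurons. Neurons without lead are not analysed here, so no value below is an effect of lead. The sample labels gave the dose as 5 mM and the study design as 5 µM, and the end of the exposure as day 13 or day 14 in vitro. The comparison made was IP against input, which asks which transcripts carried regions recovered by the antibody in exposed neurons. With 1 library per group there was no replicate check on any value, and the table of peaks held no read counts, so the depth of both libraries is unknown. All fold enrichments and p values of peaks are those of the authors' peak caller, and p is also given as a score, 10 times the −log10 of p. Coordinates are as deposited, with starts counted from 1. The genome build is not given in the sources used here, and the place of a peak within its transcript was not analysed here.

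Among genes whose name in the table was not provisional, the strongest peaks lay in Bccip (fold enrichment 84.97), Ube2k, a ubiquitin-conjugating enzyme (71.81), Gap43, the growth-cone protein of extending axons (70.97), Lrrc4b, a synaptic adhesion protein (68.71), Ddrgk1 (66.39), Xrra1 (63.38), Fam32a (62.59), Basp1, a membrane protein abundant in growing axons (61.9), and Anp32b, an acidic nuclear histone chaperone (61.33). The Hmgb1 pseudogene Hmgb1-ps33, named Hmg1l1 in the table, ranked among them at 77.69, a value left uncertain because a pseudogene can share reads with its parent gene. Each of these 10 peaks had a score of 3100, a value shared by 168 peaks. Gap43, Basp1 and Anp32b encode proteins rich in glutamate or lysine. A list of 51 other genes of such proteins was written after these peaks had been seen. Of the 51 genes, 42 had a peak (82.4%), against 17.3% of all protein-coding genes. Chromatin regulators, not chosen for composition, had 84.9%, so the share alone does not single out composition. The median highest fold of the 42 genes was 14.3, against 7.46 in random lists matched on peak number. The Gap43 peak spanned bases 62777623 to 62777868 of chromosome 11, the Basp1 peak 97357962 to 97358165 of chromosome 2, the Bccip peak 212726542 to 212726728 of chromosome 1 and the Ube2k peak 44168357 to 44168631 of chromosome 14. When provisional names were admitted, 8 of the 10 genes with the highest fold carried such a name, and the highest fold of all, 298.33, lay in one of them on chromosome 6.

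In all, 8512 peaks on 21 chromosomes were listed, and they fell in 4209 genes. The median fold enrichment was 5.9 (quartiles 4.41 and 8.45), 1475 peaks reached 10-fold and 96 reached 30-fold. The median peak was 161 bases long (quartiles 112 and 248), with a range of 1 to 7383 bases. The list was permissive: the weakest peak had a score of 3.02, which is a p of 0.499, and the false discovery rate column stood at 100% in all 8512 peaks. A p of at most 0.05 was reached by 6109 peaks (71.8%), a p of at most 1e-5 by 3896 and a p of at most 1e-10 by 2804 peaks (32.9%) in 1708 genes. For each gene list below, the number of members with a peak in the last of these sets is given beside that in the full list.

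**Figure D1:**
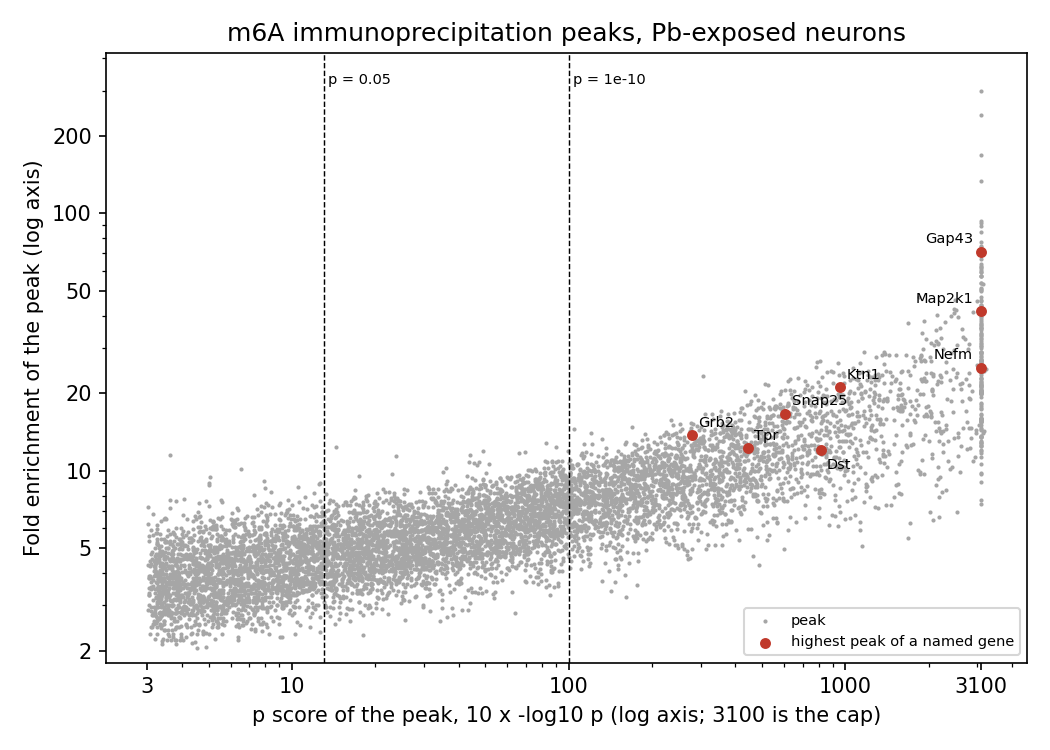
Each grey point is 1 of the 8512 peaks, with its p score on the x axis and its fold enrichment on the y axis, both logarithmic; red points are the highest peaks of named genes and dashed lines mark scores for 0.05 and 1e-10. Peaks of higher fold tended to have higher scores, 168 peaks stand at the cap of 3100 and 7 above it, and 2403 peaks lie left of the first dashed line.

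Ktn1, a kinesin-binding protein of the endoplasmic reticulum, and Tpr, a nuclear pore basket protein, had 18 peaks each. Dst, a cytoskeletal linker, had 16 and the translation initiation factor Eif4g3 had 15. Smarca2, an ATPase of the SWI/SNF remodelling complex, the scaffold Akap9 and the ciliary rootlet protein Crocc had 14 each, and Myh10, a non-muscle myosin heavy chain, and Smarcc1, another SWI/SNF subunit, had 13 each. The highest folds within these genes ranged from 12.04 in Dst to 35.81 in Myh10. Whether an enriched stretch that spans several exons was listed as several peaks was not analysed here. Peak numbers may therefore not be numbers of separate sites. Of the 4209 genes, 2317 (55.0%) had 1 peak, 896 had 2 and 996 (23.7%) had 3 or more. The highest fold of a gene was larger where a gene had more peaks, with medians of 5.45 for genes with 1 peak, 7.18 with 2, 9.32 with 3 to 5 and 12.7 with 6 or more. A gene with more peaks has more chances of a high one, so the lists below were set against random lists of genes matched on peak number. Counting peaks with a p of at most 1e-10, 247 genes had 3 or more.

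Neuron markers and presynaptic genes were often listed, and in the full list their peaks were stronger than those of matched genes. Of 20 neuron markers, 12 had a peak (60%, exact 95% interval 36.1 to 80.9%; coverage percentile 100 of 10000 random lists), among them Gap43, the neurofilament gene Nefm (25.16), Snap25, a SNARE protein of vesicle fusion (16.68), and Mapt, which encodes tau (16.51). Their median highest fold was 14.53 (interval 9.43 to 16.68) against 6.995 in matched random lists, at the 99.96th percentile of 10000 such lists. Without the markers that are among those 51 genes, a set that leaves Gap43 in, 10 neuron markers had a median of 14.27, at the 99.89th percentile. Of 42 presynaptic genes, 25 had a peak (59.5%, interval 43.3 to 74.4%; coverage percentile 100), among them the active-zone scaffold Pclo (21.49). Their median was 12.28 (interval 10.42 to 15.76) against 8.53, at the 99.4th percentile. Restricted to peaks with a p of at most 1e-10, 10 neuron markers and 21 presynaptic genes stayed listed, and the medians of 15.3 and 14.52 lay at the 96.19th and 84.21st percentiles of genes listed at that p, inside the 95% range of random lists.

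Postsynaptic genes and ion channels were also listed often, with folds near those of other genes. Of 51 excitatory postsynaptic genes, 24 had a peak (47.1%, interval 32.9 to 61.5%; coverage percentile 100), with Homer1, a scaffold of metabotropic glutamate receptors, at 17.42, the exchange factor Kalrn at 13.66, the kinase subunit Camk2b at 13.39 and the scaffold Shank1 at 12.19. Of 40 voltage-gated channel genes, 21 had a peak (52.5%, interval 36.1 to 68.5%; coverage percentile 100), with the calcium channel genes Cacna1a at 20.11, Cacnb1 at 13.44 and Cacna1e at 13.29 and the sodium channel gene Scn8a at 11.0. The list medians of 6.12 and 6.35 lay at the 28.2nd and 28.6th percentiles of matched lists. Of these, 8 postsynaptic and 10 channel genes had a peak at a p of at most 1e-10. Their medians of 12.065 and 9.295 lay at the 70.4th and 24.1st percentiles of lists matched at that p. Of 30 inhibitory synapse genes, 6 had a peak (20%, interval 7.71 to 38.6%), with the GABA-B receptor gene Gabbr2 at 29.35, Gad1, which makes GABA, at 9.96 and Calb2 at 9.59. The inhibitory list had a median of 7.7, at the 67.7th percentile, and 2 of its genes had a peak at a p of at most 1e-10.

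The title of the study names the PI3K-AKT pathway, a kinase cascade of growth and survival signalling. Of 82 core members of this cascade, 31 had a peak (37.8%, interval 27.3 to 49.2%), against 14 in the median random list of coding genes, at coverage percentile 100. Because the study of these samples names this pathway, the count is not independent evidence. The strongest were Map2k1 (41.6) and Map2k2 (18), kinases of the connected MAPK branch, Ppp2ca, the catalytic subunit of protein phosphatase 2A (37.25), and the adaptor Grb2 (13.73). The Map2k1 peak spanned bases 69431490 to 69431616 of chromosome 8 and the Ppp2ca peak 37324233 to 37324531 of chromosome 10. Further members, named after their values were seen, were Pik3r3, a regulatory subunit of the lipid kinase, at 7.93 and Akt1 at 3.86. Akt2, Mtor and Pik3ca had no listed peak. The median highest fold was 6.82 (interval 5.19 to 7.93) against 6.11 in matched lists, at the 84.2nd percentile. A p of at most 1e-10 was reached in 14 core members. Their median of 8.29 lay below the 9.655 of lists matched at that p, at the 7.49th percentile. Of 51 receptors and ligands that feed the pathway, 7 had a peak (13.7%, interval 5.70 to 26.3%; coverage percentile 25.6), the highest in Fgfr3 (6.25), Pdgfa (5.28), Pdgfd (4.78) and Ntf3 (4.5), and none had one at a p of at most 1e-10 (exact upper limit 6.98%; coverage percentile 1.13). In the pathway annotation of the table, 73 genes carried the PI3K-Akt term. By number of listed genes it had rank 5 among the 70 pathway terms with 30 or more listed genes. That rank makes no allowance for the size of each pathway. Of the 73 genes, 30 had a peak at a p of at most 1e-10. The median highest fold of the 73 genes, 6.71 against 6.31, lay at the 79.5th percentile of matched lists.

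Genes of the m6A machinery were themselves listed. Of 26 members, 10 had a peak (38.5%, interval 20.2 to 59.4%; coverage percentile 99.4). At a p of at most 1e-10, 4 had one (15.4%), inside the range of random lists at the 93.0th percentile. Zc3h13, a component of the methyltransferase complex, had 11 peaks with a highest fold of 43.31 at bases 61099837 to 61100437 of chromosome 15. The nuclear reader Ythdc1 was at 15.13, the cytoplasmic reader Ythdf3 at 8.93 and the complex member Rbm15b at 6.93. Virma, Mettl3 and Wtap were named after their values were seen. Virma, another complex member, stood under a provisional name in the table at 16.77. The catalytic subunit Mettl3 had 1 peak of 3.64-fold with a score of 4.91, and Wtap 1 peak of 3.77-fold with a score of 5.5. The demethylase genes Fto and Alkbh5 had no listed peak. The list median of 6.48 against 6.61 lay at the 46.0th percentile of matched lists.

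Among 46 genes of metal handling and oxidative stress, 12 had a peak (26.1%, interval 14.3 to 41.1%; coverage percentile 93.6), and 7 at a p of at most 1e-10. Txnrd1, a thioredoxin reductase, reached 20.52, Nfe2l2, the transcription factor of the antioxidant response, 10.84, Alas1, the first enzyme of haem synthesis, 9.43 and the metallothionein gene Mt1 8.13. The Mt1 peak lay on chromosome 17, whereas the gene of that name lies on another chromosome in the current gene table, which leaves its locus uncertain. Of 39 genes of endoplasmic reticulum stress and apoptosis, 12 had a peak (30.8%, interval 17.0 to 47.6%; coverage percentile 98.0), led by the chaperones Calr (14.71), Hsp90b1 (10.91) and Dnajb1 (8.94). Ddit3 was at 8.81 with a score of 5.02. At a p of at most 1e-10, 6 genes of this list had a peak (15.4%), inside the range of random lists at the 96.4th percentile. The medians of 7.56 and 7.10 lay at the 87.0th and 89.5th percentiles of matched lists. At a p of at most 1e-10 the medians of 8.13 and 8.49 lay below those of matched lists, 9.99 and 10.17. Their percentiles there were 9.1 and 13.2. Of 30 immediate early genes, 8 had a peak, and 2 at a p of at most 1e-10. Homer1 was at 17.42 and Nr4a3 at 9.61. Jund was at 6.05 with a score of only 5.14, and Egr4 at 4.94 with a score of only 7.8. The list median of 4.77 lay at the 6.4th percentile.

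Chromatin regulators had the largest share of listed members of the 21 lists. Of 53, 45 had a peak (84.9%, interval 72.4 to 93.3%; coverage percentile 100), with 156 peaks in all, and 27 had one at a p of at most 1e-10. The remodelling ATPases Chd5 (42.21), Smarca2 (31.87), Chd3 (26.31) and Smarca4 (23.19) were highest. Their median of 8.37 against 8.01 lay at the 67.2nd percentile of lists matched on peak number. Axon guidance genes were listed in 17 of 51 cases (33.3%, interval 20.8 to 47.9%; coverage percentile 99.7), with Robo2 at 19.75, Epha7 at 15.51, Ephb1 at 15.44 and Plxnb2 at 13.25, and Wnt and Notch genes in 11 of 42, with Tcf7l2 at 14.28, Tcf7l1 at 7.48, Fzd3 at 7.31 and Dvl3 at 7.03. Their medians of 5.99 and 5.35 lay at the 29.6th and 20.2nd percentiles. At a p of at most 1e-10, 6 axon guidance genes had a peak (11.8%), inside the range of random lists at the 89.5th percentile. The median of these genes, 14.345, lay at the 91.5th percentile of lists matched at that p. Of the Wnt and Notch genes, 2 had a peak at that p. Matrix and integrin genes had weak peaks: 13 of 52 were listed, with Col6a2 at 11.6, Lamc1 at 9.3, Fn1 at 7 and Lama3 at 6.71, and the median of 4.8 (interval 3.2 to 7) against 7.27 lay at the 0.41st percentile of matched lists. At a p of at most 1e-10, 5 matrix genes stayed listed and their median of 7 lay at the 0.91st percentile.

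Genes of housekeeping complexes and markers of other cell types had shares of listed members inside the range of random lists. Of 76 ribosomal protein genes, 12 had a peak (15.8%, interval 8.43 to 26.0%), and of 50 oxidative phosphorylation genes, 8 (16%, interval 7.17 to 29.1%), against 17.3% of all 23154 protein-coding genes (interval 16.8 to 17.8%). Rpl35 was at 15.03, Rpl23a at 13.08, Rpl26 at 10.92 and Rpl24 at 10.01, and the ribosomal median of 7.76 lay at the 97.85th percentile of matched lists and, without matching on peak number, at the 79.2nd. Ribosomal protein genes have many processed copies, so their values are uncertain. Ndufb9 was at 16.42, Ndufv2 at 7.74, Ndufa6 at 6.77 and Uqcrb at 6.65. The Uqcrb peak had a score of only 4.66 and lay on another chromosome than the gene. The coverage percentiles were 37.6 for ribosomal and 42.4 for oxidative phosphorylation genes. At a p of at most 1e-10, 4 ribosomal and 2 oxidative phosphorylation genes had a peak. Peaks lay in 3 of 15 astrocyte markers (Slc4a4 at 8.39, Fgfr3 at 6.25 and Sox9 at 5.78). The oligodendrocyte lineage had 1 of 16 (Cnp at 5.59 with a score of only 6.96). Microglia had 2 of 15 (Aif1 at 6.34 and C1qa at 3.52) and vessels and fibroblasts 1 of 15 (Col3a1 at 7.2). At a p of at most 1e-10, 1 astrocyte marker and 1 vascular or fibroblast marker had a peak, and 0 of the oligodendrocyte lineage or microglia. Across the 21 lists, 9 had a share above the central 95% of random lists of coding genes and 0 below. That reference includes genes neurons do not express, so the shares mix expression with recovery by the antibody. Of the 17 lists with 5 or more listed members, 3 had a median fold above and 1 below the central 95% of matched lists, where 0.85 would fall outside by chance. The lists of neuron markers and presynaptic genes, both above, share genes and are not independent.

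**Figure D2:**
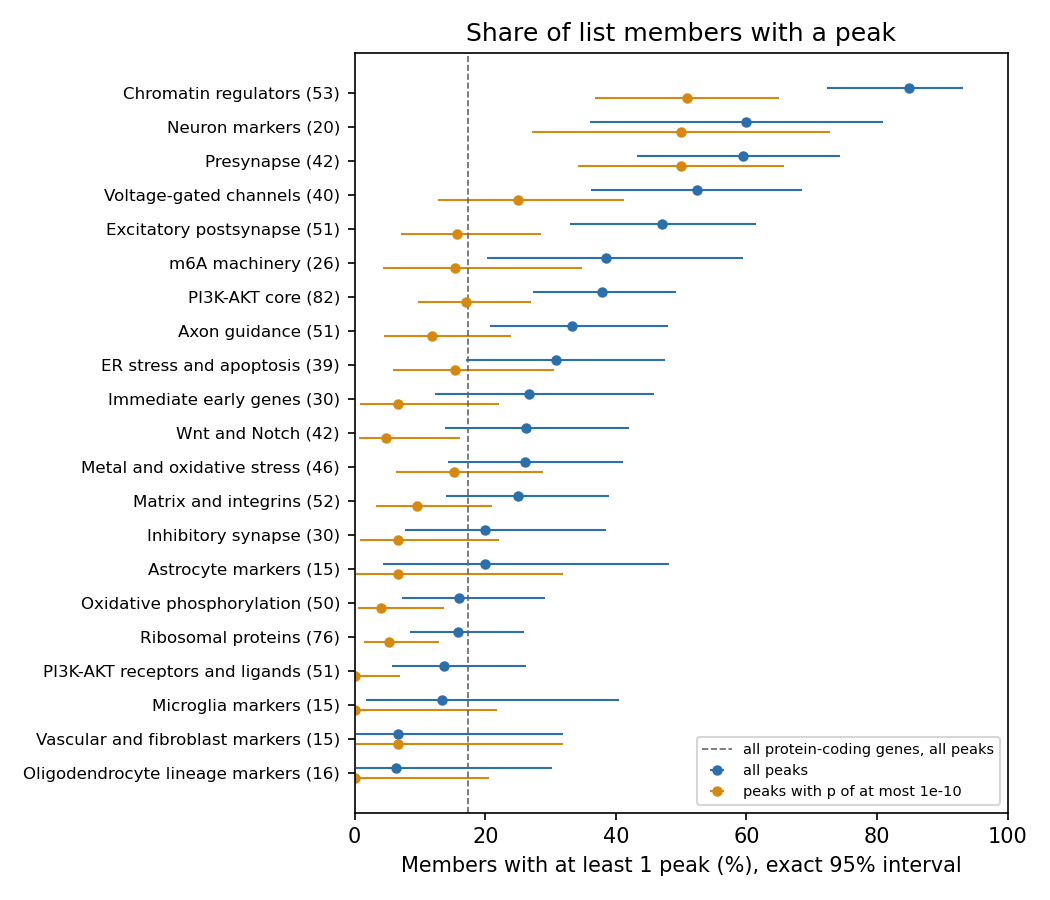
The x axis gives the percentage of each list's members with at least 1 peak, with exact 95% intervals, for all peaks (blue) and for peaks with a p of at most 1e-10 (orange); the number of members follows each name, and the dashed line marks the 17.3% of all protein-coding genes with a peak. Chromatin regulators stand highest at 84.9% and oligodendrocyte lineage markers lowest at 6.25%.

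**Figure D3:**
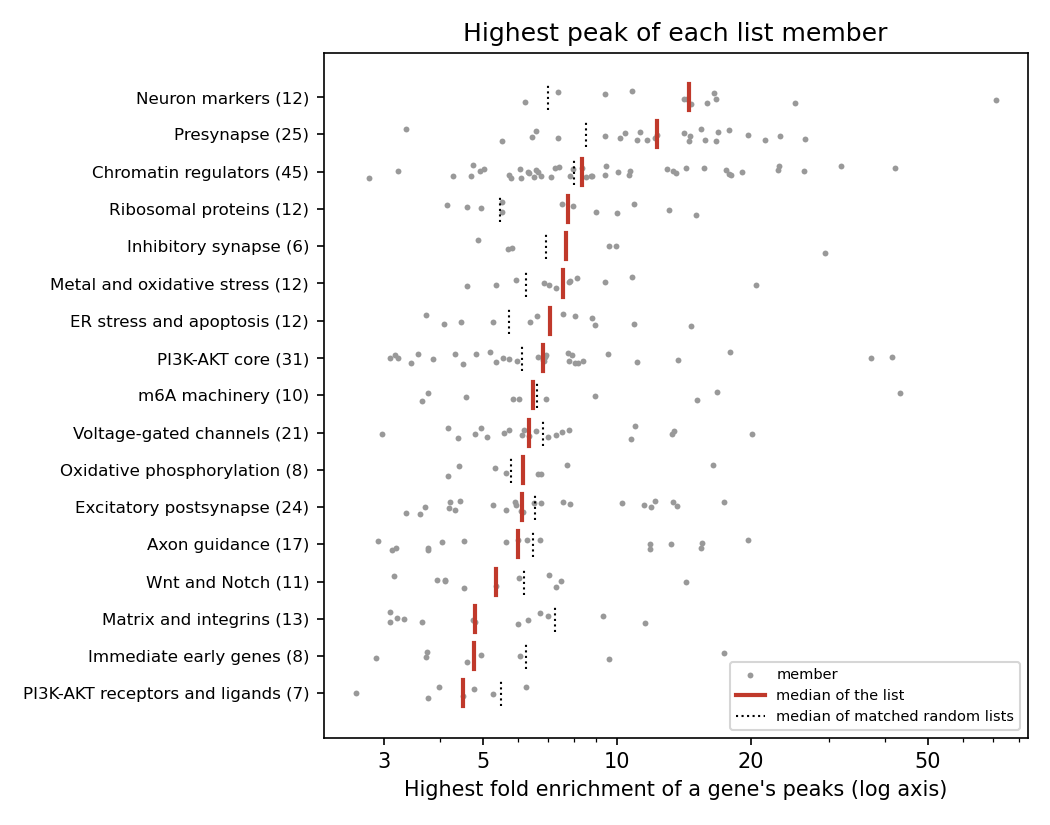
Each grey point is the highest fold enrichment of 1 listed gene on a logarithmic axis, for the 17 lists with 5 or more listed members, whose number follows each name; red bars are list medians and dotted bars the medians of random lists matched on peak number. Neuron markers (14.53 against 6.995) and presynaptic genes (12.28 against 8.53) lie right of their dotted bars and matrix genes (4.8 against 7.27) left.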

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

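The settings of a p of at most 1e-5 and of the removal of doubtful names were chosen after the data were seen. The number of peaks (8512) and of genes with a peak (4209) stayed within 1.5 times under the p limit 10 times below the largest p, the minimum of 4.1-fold, merging and the removal of doubtful names, and moved to 3896 peaks in 2213 genes at a p of at most 1e-5 and to 2804 in 1708 at 1e-10. Genes with 3 or more peaks went from 996 to 247 at 1e-10. No region overlapped or touched another, so merging and the overlap required changed nothing. Of 21 list shares, 17 kept their place inside or outside the random range at 1e-10 and 19 at 1e-5. Those that left the upper range were the m6A machinery (15.4% at 1e-10), endoplasmic reticulum stress and apoptosis (15.4% at 1e-10) and axon guidance (11.8% at 1e-10 and 13.7% at 1e-5), while receptors and ligands of PI3K-AKT fell under the lower bound at 0% in both settings. Of 17 fold medians, the mean over a gene's peaks and the removal of doubtful names changed no place. At 1e-10, 10 lists kept 5 or more members, and neuron markers (median 15.3) and presynaptic genes (14.52) came inside the random range. The medians of their matched random lists were 11.28 and 12.82 there, against 6.995 and 8.53 in the full list. Without matching on peak number, ribosomal proteins (7.76) came inside the range and chromatin regulators (8.37) went above it, at the 98.7th percentile. The cause of these shifts was not tested. Depth is unknown, so peaks missing from transcripts of low abundance cannot be told from missing methylation. The planned transcript region, motif and exonic length settings were not run, and p stood in for a false discovery rate that was 100% throughout. No paired analysis was possible because each group held 1 library, which also left no replicate to leave out.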

Other observations

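The term comparison and the tests on doubtful names and on coiled-coil genes were chosen after the result was seen; the list of glutamate- and lysine-rich proteins was written before the values of its members were seen. Other gene groups differed in the strength of their peaks. Among 288 pathway and Gene Ontology terms with 30 or more listed genes in the table's own annotation, 34 had a median highest fold above the central 95% of random lists matched on peak number and 9 below, where 7.2 on each side would come by chance. The 540 genes of poly(A) RNA binding stood high, with a median of 8.53 against 7.2, above all 10000 random lists. Terms of RNA processing went different ways: the 71 genes of the pathway term spliceosome had 9.07 against 7.46 (99.6th percentile) and mRNA splicing via the spliceosome (56 genes) 8.66 against 7.21 (98.6th percentile), RNA splicing (45 genes, 62.1st percentile) and mRNA processing (62 genes, 75.3rd percentile) lay inside the random range, and ribosome biogenesis (31 genes, 5.81 against 7.39, 1.37th percentile) lay below it. Protein processing in the endoplasmic reticulum (57 genes, 8.82 against 6.53, percentile 100), the synaptic vesicle (44 genes, 9.90 against 6.76, percentile 100) and histone binding (43 genes, 10.23 against 7.82, 99.4th percentile) also stood high. The 100 genes of positive regulation of GTPase activity stood low, at 5.75 against 7.10, below all random lists. Terms share genes and are not independent.

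Doubtful gene names were more frequent among the highest folds: of the 85 peaks in the top 1% by fold (31.86 or more), 16 had a provisional name, no match to a current gene or a gene on another chromosome (18.8%, exact 95% interval 11.2 to 28.8%), against 6.14% of the rest (interval 5.63 to 6.67%). Reads shared between copies of a gene, such as retrocopies, could give these 16 peaks, but counting names cannot show shared reads. The other 69 of the 85 peaks had no such doubt. Over all peaks, those with unmatched names had a median fold of 5.89 and those of a gene on another chromosome 6.95. The other matched peaks had a median of 5.9. Of the 85 peaks, 0 had a p above 1e-5. Fold and score rose together across peaks (Spearman 0.834), so that was likely beforehand and is no separate test. The number 85 is also 1% of the full permissive list, so the part played by the p limit cannot be decided from this count. How reads with several matches were placed is not given in the sources used here, and no biological explanation was tested.

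Genes of coiled-coil protein families were listed more often than zinc finger genes, many of which have a long last exon, a usual place of m6A. Of 241 genes named Ccdc, Cep, Kif, Golga or Myh with a number, 96 had a peak (39.8%, interval 33.6 to 46.3%), against 54 of 424 named Zfp or Zbtb (12.7%, interval 9.71 to 16.3%). The zinc finger share rested mostly on Zfp (43 of 380, 11.3%), while Zbtb (11 of 44, 25%, interval 13.2 to 40.3%) overlapped the interval of Ccdc (45 of 136, 33.1%, interval 25.3 to 41.7%). The permissive p limit is argued against as the whole cause of the pooled difference, since at a p of at most 1e-10 the shares were 22.4% (interval 17.3 to 28.2%) and 4.01% (interval 2.35 to 6.34%). A greater chance of a peak in genes of many exons stays open, as listed coiled-coil genes also had 3.55 peaks each against 1.48, and so do expression, transcript length and methylation itself.

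Gap43, Basp1 and Anp32b, among the genes with the strongest peaks, encode proteins rich in glutamate or lysine, whose codons consist of purines, and anti-m6A antibodies are known to recover some purine-rich RNA. A list of 51 other genes of such proteins was written from background knowledge of their composition; genes already seen at the top were left out, so none is among the 60 genes with the highest fold, and Hmgb1 was included although its pseudogene had been seen. Of these, 42 had a peak (82.4%, interval 69.1 to 91.6%), above the ribosomal (upper bound 26.0%) and oxidative phosphorylation lists (29.1%), and their median highest fold was 14.3 against 7.46, at percentile 100 of 10000 matched lists and at the 99.1st percentile at a p of at most 1e-10; Upf3b (33.15), Nap1l1 (28.15), Ppig (27.89) and Eif3a (27.88) were highest. Without the 5 genes shared with the other lists the median was 14.23, again above all random lists. The share of listed genes cannot decide, because chromatin regulators, not chosen for composition, had 84.9% listed with a median at the 67.2nd percentile. The high median fold fits the hypothesis that the antibody recovered purine-rich coding sequence. Methylation of these same transcripts, their abundance and their length stay open, because no sequence, input level or motif could be examined.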
